A study of Mus musculus with 6 samples.

How the data were processed

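Total RNA of 6 mouse spleens, 3 from EAE mice and 3 from PBS controls, was hybridised to 1-colour (Cy3) Agilent arrays, 1 array per mouse. Per the labels' protocols, RNA was extracted with TRIzol from the spleen of each mouse and amplified into labelled cRNA by random priming, and RNA integrity was assessed on a denaturing gel. Groups and replicate numbers were taken from the sample titles. Each array stands for a separate mouse, so the spread within a group is between mice and includes array error. In EAE it also includes any difference between scans.

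Scanner files held intensity values that, per the file headers, were made with Agilent Feature Extraction 11.0.1.1 (also named in the submitters' processing notes), protocol GE1_1100_Jul11. The processed signal is background-subtracted and detrended within the array, per the file headers, and is not normalized between arrays. The headers name genome build mm9 for the array design. The authors also deposited a table of log2 values for 60804 probes, with a column for each array. Its column medians were all 6.03, and it differed from quantile-normalized log2 processed signals by a median of 0.00073, so its scale was read as log2 with quantile normalization between arrays. The tool and filters behind it are not given in the sources used here. It lacks the 15 RefSeq-named probes and was used as an alternative.

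Of the 62939 spots on an array, 61200 were non-control spots outside the 15 negative-named probes, which were set aside as background after the files had been seen. In all, 138 spots with outlier flags were left out, and 0 were saturated. The main values were log2 processed signals minus the 75th percentile of the array, with spots of a probe averaged. Dividing by the 75th percentile removes the difference in overall brightness, but not differences that depend on brightness. Low signals are set to a floor by the scanner software, so folds of dim probes depend on the background correction. Probes well above background on at least 3 of 6 arrays (41178 of 60915) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, EAE against PBS, no covariates), with two-sided p-values adjusted by the Benjamini-Hochberg method at 0.05. A probe not well above background on any array of a group was given a bound, the mean of the bright group over the mean, per array, of the higher of the lowest signal well above background and its own signal. Counts of called probes by fold size, a choice made after seeing the data, used signals in which each spot not well above background was raised to the lowest signal well above background on its array, where that was higher. On arrays the number of mice limits the precision. Signal over background, as the 75th percentile over the median of the negative-named probes, was 74.8, 102 and 77.0 in PBS and 52.1, 52.8 and 76.3 in EAE.

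Gene names were available here through RefSeq accessions alone. All 15 matched the RefSeq gene table (GRCm38.p6, used for names only) without versions, with 20 spots per probe. Other probes were kept under the IDs in the files and their coding class was not used here, so counts of mRNA probes cover the 15 and counts of lncRNA probes cover those named as lincRNAs. Of 34 gene lists fixed before the data were examined, 1 had a member on the array with a name (Tfrc, in the erythroid list), so no list was tested. lncRNAs were not set against associated mRNAs. The rule for named genes, fixed before the data were examined, took the 8 protein-coding and the 4 noncoding RNAs with the largest changes in each direction among calls without overlap. With 15 named genes all were given, and the noncoding RNAs were reduced to 2 in each direction because the files pair them with no gene.

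The fit was tested on simulated arrays of 41178 probes with known changes. It recovered 12% of changed probes at a log2 fold of 1, 64% at 2, 88% at 3 and 64% at -2, and 6 of its 120 calls were false. The simulation changed 50 probes at each fold, with far fewer calls than the 3622 in the data. It also gave both groups the same spread, so these shares do not carry over to the reported fit. Alternatives fixed before the data were examined were quantile normalization, the authors' table, no filter on dim probes, a filter on all 6 arrays, the replicate number or the scan as a block, an intensity trend with a robust prior, array weights, and each array left out. The planned normexp correction used a mean signal column not analysed here, so normexp (offset 50) on median signals was used, alone and with quantile normalization. These, cyclic loess, median scaling and limma's camera test (preset correlation 0.01, or estimated) on 5 probe sets given by the probe names were chosen after seeing the data. Normexp moved the median log2 difference of all tested probes from -0.02 to 0.14. Tests of single values were exact permutation tests, which cannot go below p = 0.1 with 3 against 3 arrays. Position on the slide followed the groups and could not be separated from them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.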

Results

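Spleens of 3 mice with experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis, were compared with spleens of 3 control mice. All were female C57BL/6 mice aged 12 weeks. The EAE mice had been immunized with a peptide of myelin oligodendrocyte glycoprotein at 2 mg/mL and given 200 ng of pertussis toxin. The sample titles and the treatment protocol give different residue ranges for the peptide. Control mice received phosphate-buffered saline (PBS) in place of the peptide, and the labels leave open whether they received the toxin. RNA of each spleen was hybridised to its own 1-colour array for long noncoding RNAs (lncRNAs) and mRNAs. Each array carried 62939 spots and 60915 non-control probes, of which 41178 were well above background on at least 3 of the 6 arrays and were tested.

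EAE arrays were dimmer than PBS arrays. The 75th percentile of the processed signal was 495, 568 and 429 on the PBS arrays and 278, 329 and 394 on the EAE arrays, a log2 difference of -0.58 (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays allow). Probes well above background made up 69.2% ± 1.54 (SD, n = 3) in PBS and 61.6% ± 3.40 in EAE (exact two-sided permutation p = 0.1). Each array was scaled to its own 75th percentile before any comparison. Control spots for the ends of GAPDH transcripts also differed between the groups. The mouse 3′ spots exceeded the 5′ spots by 1.12 ± 0.07 on the log2 scale in PBS and by 1.36 ± 0.15 in EAE (SD, n = 3), and every EAE array lay above every PBS array (exact two-sided permutation p = 0.1). At rat and human GAPDH spots the 3′ minus 5′ difference was higher in EAE by 0.55 and 0.57 (exact two-sided permutation p = 0.1 each). Every EAE array again lay above every PBS array, at the rat spots narrowly (-0.300 on EAE 2 against -0.309 on PBS 2). The rat 3′ spots lay below the 5′ spots on every PBS array. The spot names were read as giving the transcript end.

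**Figure D1:**
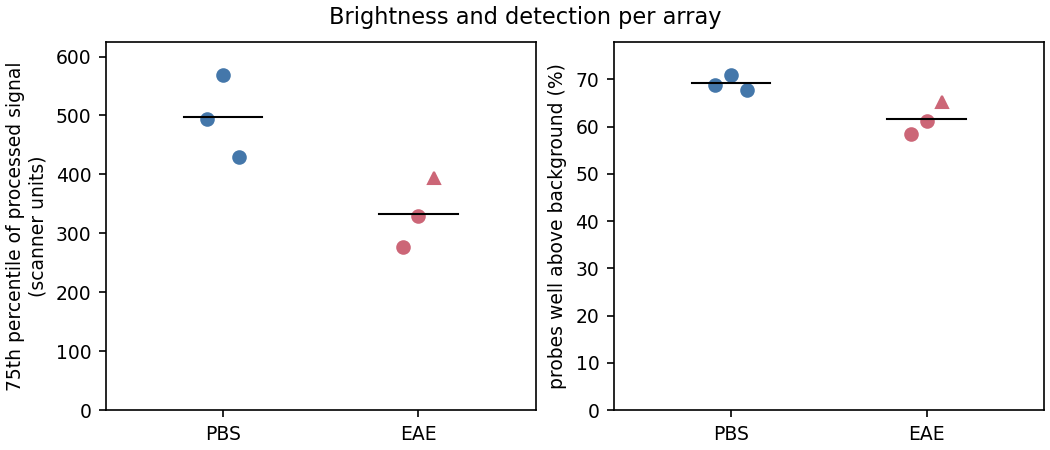
The 75th percentile of the processed signal in scanner units (left) and the percentage of probes well above background (right) for each array, with bars at the group means. Circles are the 5 arrays of the first scan and the triangle is EAE 3 of the second scan, and every EAE array lies below every PBS array on both measures.

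The series asked which mRNAs and lncRNAs differ in the spleen between EAE and normal mice. The files pair 15 probes with RefSeq transcripts, mostly of widely expressed genes, and these are the only probes with gene names here. The counts of named genes cover these 15 alone and do not answer the question for mRNAs in general. Of these 15 genes, 1 was lower in EAE and 0 were higher, both over all probes tested and adjusted over the list alone. Actb, which encodes the cytoskeletal protein beta-actin, was 2.61-fold lower in EAE spleens. Its log2 level fell by 1.39 ± 0.23 (SE, n = 3 per group), from 6.87 ± 0.16 (SD) in PBS to 5.48 ± 0.36 in EAE, with a limma adjusted p of 0.0116. All 3 EAE arrays lay below all 3 PBS arrays, and the unnormalized signal of Actb was 50941 to 72909 in PBS and 10216 to 19414 in EAE. The call was lost without PBS 2 (adjusted p = 0.0639) and without PBS 3 (adjusted p = 0.0502), and over all 17 alternatives the adjusted p ranged from 0.0014 to 0.0639. The dimmer EAE arrays and the GAPDH end differences of 0.24 (mouse), 0.55 (rat) and 0.57 (human) accompany this value. Each end difference was smaller than the fall of Actb.

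G6pd2, a retrotransposed copy of the glucose-6-phosphate dehydrogenase gene, had a log2 difference of 1.13 ± 0.32 (SE) with no overlap between the groups after scaling. It missed the threshold (limma adjusted p = 0.0708, and 0.0618 over the list alone). Its unnormalized signals overlapped, at 690 to 832 in PBS and 718 to 1490 in EAE. G6pd2 was past the threshold in 7 of the 17 alternatives, among them the one without EAE 2 (log2 1.44, adjusted p = 0.0214). Without EAE 1 it had 0.79 (adjusted p = 0.0965). Over the alternatives its adjusted p ranged from 0.0214 to 0.219. The probe could also bind RNA of the related G6pdx gene, so its signal is uncertain. Tfrc, which encodes the transferrin receptor and is the only member of the erythroid list with a gene name here, had a log2 difference of -0.60 ± 0.31 (adjusted p = 0.269). The lactate dehydrogenase family gene Ldhal6b had 0.48 ± 0.20 (adjusted p = 0.187) and passed in 1 alternative, with background corrected by normexp (adjusted p = 0.0486, within a range of 0.0486 to 0.392).

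The remaining 11 named genes did not pass the test in the reported fit or in any alternative. Gusb, a lysosomal enzyme gene, and the tubulin gene Tuba1b had log2 differences of 0.44 ± 0.22 and 0.37 ± 0.19. The glycolytic gene Gapdh had 0.30 ± 0.21 and the purine salvage gene Hprt 0.25 ± 0.18, both with the sign turned under cyclic loess. Ppia had 0.17 ± 0.19, the ribosomal protein gene Rpl13a 0.08 ± 0.20 and the MHC class I light chain gene B2m 0.07 ± 0.17, and all 3 signs turned under quantile normalization and cyclic loess. The glycerol kinase gene Gk had -0.02 ± 0.21, with the sign turned under cyclic loess and median scaling. The chaperone gene Hsp90ab1, the RNA-binding protein gene Nono and the TATA-binding protein gene Tbp had -0.15 ± 0.21, -0.18 ± 0.25 and -0.26 ± 0.20. Over the 15 genes the median log2 difference was 0.08, and 12 lay between -0.5 and 0.5.

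**Figure D2:**
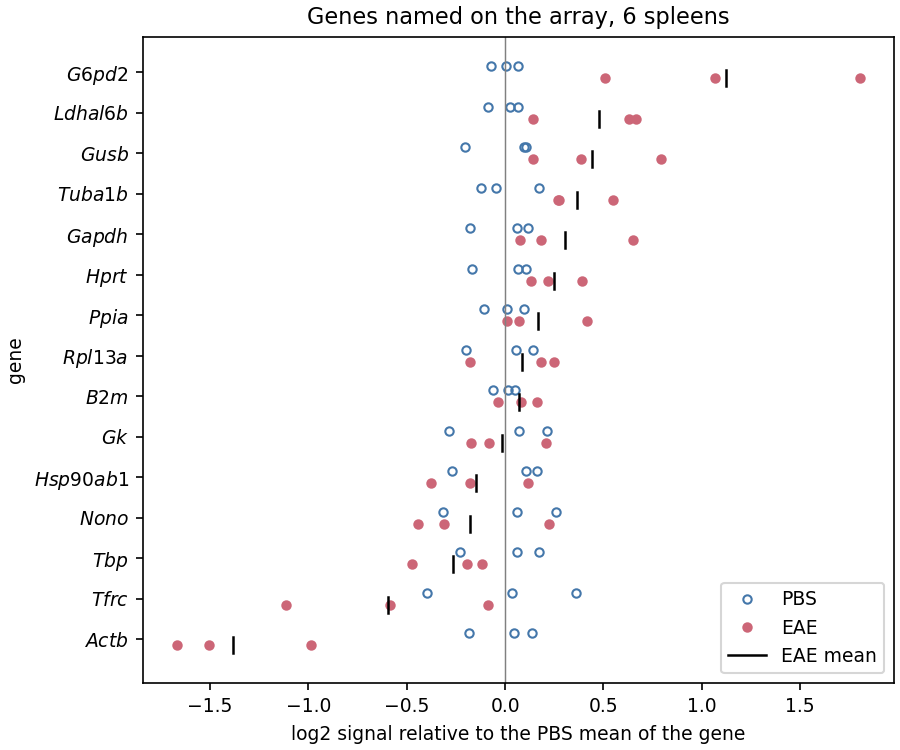
Log2 signal of the 15 named genes on each array (x axis), relative to the PBS mean of the gene, with open circles for PBS, filled circles for EAE and a bar at the EAE mean. Actb is the gene past the threshold, at -1.39, and G6pd2 has the largest positive value, at 1.13.

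Long intergenic noncoding RNAs (lincRNAs) could be recognised from the names of 1836 probes, of which 573 were tested. In EAE spleens 41 were higher and 11 were lower (limma, adjusted over all probes), and adjusted over the list alone 42 were higher and 13 lower. With spots not well above background raised to a floor, 38 of the higher probes differed at least 2-fold, 19 at least 4-fold and 4 at least 8-fold, and of the lower probes 8, 1 and 0. Among the lincRNA probes called with normexp these counts were 29, 11 and 2 higher and 11, 1 and 0 lower. The probes fell into 3 name families. Probes named for mouse lincRNAs gave 11 higher and 4 lower of 204 tested, probes named for human lincRNAs gave 24 and 6 of 329, and probes named for mm9 lincRNA exons gave 6 and 1 of 40. The share of lincRNA probes called was 9.08%, against 8.79% of the other tested probes (odds ratio 1.04, 95% interval 0.762 to 1.38, Fisher's exact two-sided p = 0.824). Of the called lincRNA probes 78.8% were higher, against 69.5% of the other called probes (odds ratio 1.63, 95% interval 0.821 to 3.54, Fisher's exact two-sided p = 0.172). Both Fisher tests treat probes as independent, which probes measured on the same arrays are not, so the intervals may be too narrow. The median log2 difference was -0.14 over the lincRNA probes and -0.02 over the other tested probes, and the test of this shift missed the threshold (limma camera, adjusted p = 0.218, and adjusted p = 0.605 with an estimated correlation). Fewer lincRNA probes were well above background on each EAE array (23.5%, 25.2% and 30.1%) than on any PBS array (31.3% to 36.8%). The same held for all probes (58.5%, 61.2% and 65.2% in EAE, 67.9% to 70.9% in PBS), on EAE arrays that were dimmer.

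The lincRNA counts changed when 1 array was left out, which also leaves fewer arrays to detect a difference. Without PBS 1 there were 32 calls (3 lower), without PBS 2 there were 34 (1 lower) and without PBS 3 there were 47. Leaving out EAE 1, 2 or 3 gave 55, 59 and 65 calls. The number of lower lincRNA probes was 18 without PBS 3, 19 without EAE 2 and 25 without EAE 3. With background corrected by normexp, 63 lincRNA probes were higher and 21 lower.

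The 2 highest and the 2 lowest called lincRNA probes by fitted log2 difference, without overlap between the groups, are given by their probe names. In the dimmer group most of their arrays were not well above background, so the sizes and, for the rises, their order depend on the background correction. On the processed signals, the probe humanlincRNA1025-_P1 was at least 4.61-fold higher in EAE, where it was well above background on 3 of 3 arrays against 0 of 3 in PBS (limma adjusted p = 0.00126). The probe humanlincRNA0644-_P1 was well above background on 3 of 3 EAE arrays and 1 of 3 PBS arrays, and was higher in EAE with a fitted log2 difference of 3.91 ± 0.54 (adjusted p = 0.00537). Both passed in all 17 alternatives. The bound holds for the processed signals alone, since the log2 differences of the 2 probes were 1.46 and 2.08, in the opposite order, when the background was corrected by normexp, and 1.13 and 1.91 with quantile normalization added. The probe mouselincRNA1453-_P1 fell by 3.80 ± 0.87 on the log2 scale, and was well above background on 1 of 3 EAE arrays (adjusted p = 0.0376). It passed in 6 of 17 alternatives, and the calls without PBS 1 (adjusted p = 0.107), PBS 2 (0.147), EAE 1 (0.0992) and EAE 3 (0.0793) were lost. The probe mouselincRNA0499+_P1 fell by 2.11 ± 0.44, was also well above background on 1 of 3 EAE arrays (adjusted p = 0.0277) and passed in 12 of 17 alternatives. Its call was lost without PBS 1 (adjusted p = 0.0865), PBS 2 (0.113), PBS 3 (0.0736) and EAE 1 (0.0628). The log2 falls of these probes were -1.27 and -0.69 when the background was corrected by normexp, and -1.48 and -0.94 with quantile normalization added. Over the alternatives the adjusted p ranged from 0.000747 to 0.147 for mouselincRNA1453-_P1 and from 0.00993 to 0.113 for mouselincRNA0499+_P1.

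Over all 41178 tested probes, most of them without a gene name here, 3622 (8.80%) differed between EAE and PBS spleens in the limma test at an adjusted p under 0.05. Of these 2523 were higher in EAE and 1099 lower. With spots not well above background raised to a floor, 727 higher and 34 lower probes differed at least 4-fold, and 204 higher and 1 lower at least 8-fold. Among the probes called with normexp these counts were 413 and 16 at 4-fold and 94 and 0 at 8-fold. Groups did not overlap for 33.0% of tested probes and for 3618 of the 3622 called. Averaged over the 10 splits of the 6 arrays, the share of tested probes is 10%. Probes of an array vary together, so a single split can exceed that average by chance. A fold of at least 2 with an unadjusted p under 0.05 was met by 2208 higher and 1920 lower probes, 4128 in all, and by 2246 with background corrected by normexp and 2103 with normexp and quantile normalization. Probes well above background on every EAE array and on 0 PBS arrays numbered 109, and the reverse numbered 1184, on EAE arrays that were dimmer.

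Replicate spread was larger in EAE, with a median SD of 0.32 on the log2 scale against 0.18 in PBS and a larger SD in EAE for 75.7% of probes. The first principal component held 54.7% of the variance and placed the 3 PBS arrays on one side and the 3 EAE arrays on the other. The 3 PBS arrays and EAE 1 and 2 shared a scan, and EAE 3 was scanned apart, so the larger EAE spread may include a scan difference. Within the shared scan, which equals the fit with the scan as a block, 2275 probes were higher and 1059 lower. The count of calls was 1549 without PBS 1 (1215 higher, 334 lower), 1412 without PBS 2 (1204 higher, 208 lower) and 1770 without PBS 3 (1317 higher, 453 lower). Without EAE 2, 2663 were higher and 2009 lower. Testing all probes without the filter on dim ones gave 1784 higher and 473 lower, and normexp gave 3958 higher and 1402 lower.

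**Figure D3:**
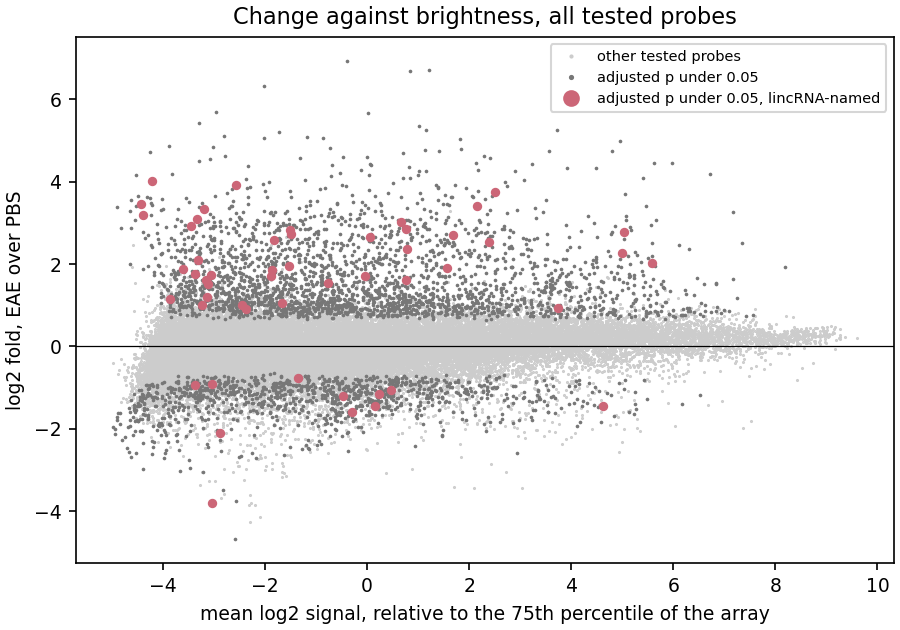
Log2 fold of EAE over PBS (y axis) against the mean log2 signal relative to the 75th percentile of the array (x axis) for tested probes. Probes among the 41178 tested that lack a value on an array are not drawn. Dark grey points are the probes with an adjusted p under 0.05 and large red points are those of them with lincRNA names. In all 52 lincRNA probes were called, 41 above 0 and 11 below.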

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

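The test in this part was chosen after the result was seen. The E1A control spots, which the report does not use, held a signal above the level of the PBS arrays. The control probe (+)E1A_r60_a107, made for a viral spike-in RNA, was 6.44-fold brighter in EAE (log2 2.69 ± 0.34, SE, n = 3 per group, limma adjusted p over 24 control probes 0.000525). Its unnormalized signal was 176, 329 and 194 in PBS and 523, 1479 and 1157 in EAE, so the dimmer EAE arrays run against the difference. More of a spike-in mix in the EAE samples would raise the other 9 E1A probes too, but 1 of them, (+)E1A_r60_a22, was well above background on all 3 EAE arrays. Its log2 difference after scaling was 0.44 ± 0.24, with every EAE array above every PBS array (adjusted p = 0.199), far below 2.69, and its unnormalized signal was 33.7 to 36.1 in EAE and 37.2 to 41.1 in PBS. Binding of a spleen transcript that differs between the groups may account for the signal and was not tested.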

How the results depend on the processing

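The alternatives with normexp, cyclic loess and median scaling were chosen after seeing the data. The planned normexp on mean signals, the gene list shifts and the lncRNA-mRNA pairs were not run. Calls shared with the reported fit kept their direction in all 18 settings, which fits of the same arrays nearly ensure. Shared calls were 38.6% of the reported calls without PBS 2, 41.2% without PBS 1 and 43.8% without PBS 3. They were 55.6% without the filter on dim probes and 67.3% to 95.4% in the other settings. Actb kept its direction in all 17 settings with its probe and its call in 15. Without the filter on dim probes 2257 probes were called (473 lower, 6 lincRNA lower), with more probes tested. Named-gene calls numbered 2 with the filter on all 6 arrays, the replicate block, the trend and robust prior, array weights, and normexp with quantile, and 3 with normexp. Lower lincRNA probes numbered 25 with the scan as a block, 19 with array weights, 17 with normexp and quantile and 7 with cyclic loess. Normexp gave 3958 higher probes, 84 lincRNA calls (63 higher, 21 lower) and 2246 probes past a fold of 2, and normexp with quantile 2103. Leaving out each array gave 1412 to 4672 calls (1204 to 2663 higher, 208 to 2009 lower), 32 to 65 lincRNA calls (29 to 42 higher, 1 to 25 lower), 0 to 2 named-gene calls and 3497 to 5000 probes past a fold of 2. Small differences of genes that were not called turned sign. B2m was -0.19 with quantile, -0.040 with normexp, -0.20 with both and -0.27 with cyclic loess. Ppia was -0.10, -0.11 and -0.19 with quantile, normexp with quantile and cyclic loess. Rpl13a was -0.14 with quantile, -0.0054 with normexp, -0.13 with both and -0.16 with cyclic loess, and -0.016 to 0.21 with an array left out. Gk was 0.017 with the scan as a block, 0.15 with array weights, 0.024 with cyclic loess and 0.030 with median scaling, and -0.16 to 0.090 with an array left out. Gapdh was -0.028 and Hprt -0.012 with cyclic loess. The cause was not tested. The replicate block gave 2177 higher and 1563 lower probes (58.2% higher) and 29 lower lincRNA probes. Deviations of same-numbered arrays correlated at 0.15, 0.04 and -0.14, and not every array correlated best with its own number, so the numbers were not taken as pairs. Signal over background was lowest on EAE 1 and 2 (52.1 and 52.8), which limits dim probes most.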

Other observations

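Of the tests in this part, those of the share of higher calls and of Actb were chosen after the result was seen. Control spots for phosphoglycerate kinase 1, a glycolytic enzyme, had a log2 difference of 0.79 ± 0.26 (SE, n = 3 per group) at the mouse 3′ probe, with every EAE array above every PBS array and a limma adjusted p over 24 control probes of 0.0604. The unnormalized signals overlapped, at 26818 to 32221 in PBS and 28081 to 38914 in EAE. The mouse GAPDH 3′ control spots had 0.24 ± 0.26 (adjusted p = 0.435), and the named Gapdh probe 0.30 ± 0.21.

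The lincRNA probes come as pairs for the 2 strands of a locus at 876 loci. Both strands were tested at 95 loci, 1 strand at 352 and neither at 429. The hypothesis that the 2 strands of a locus change together was set before its result was seen. Across the 95 loci, which are not independent replicates, the log2 folds of the strands had a Spearman rho of -0.0411 (permutation p = 0.69, two-sided), and -0.0354 under cyclic loess. Both strands were called at 1 locus, in opposite directions. These values gave no sign of a shared change of the 2 strands at the 95 loci. Neither strand was called at 79 of them, so a weak shared change, or one at the other loci, could go unseen.

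Most called probes were higher in EAE (69.7%), a share that ranged from 57.0% without EAE 2 to 85.3% without PBS 2. At a fold of at least 2 with an unadjusted p under 0.05, the directions lay closer, at 2208 higher and 1920 lower probes. These counts were 2504 and 2496 without EAE 2 and 2112 and 1385 without PBS 2. A difference between arrays that depends on brightness would lose the majority of higher calls under cyclic loess. The lowest share over cyclic loess with all arrays and without each was 62.6%. A scan effect would lose it within the scan that held both groups, where the share was 68.2%. The detection limit on the dimmer EAE arrays would lose it among bright probes. For the 10295 tested probes above the 75th percentile of the mean level, nearly all well above background on all 6 arrays, the share was 80.1%. At the lowest it was 77.4% with an array left out. These shares come from 75th percentile scaling, which leaves differences that depend on brightness. The share among bright probes under cyclic loess was not computed, so these shares do not set the detection limit aside. Position on the slide and a different mix of spleen cells in EAE mice may each contribute and were not tested.

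The fall of Actb may come from the arrays, the RNA or the spleens. A difference between arrays that depends on brightness would shrink under cyclic loess, but Actb had -1.64 ± 0.27 there (adjusted p = 0.0145), and -1.88 to -1.43 with an array left out (adjusted p = 0.0112 to 0.0666), beyond its largest SD within a group (0.46). Loss of transcript 5′ ends stays open. The GAPDH 3′ minus 5′ difference was higher in EAE by 0.24 at the mouse, 0.55 at the rat and 0.57 at the human spots. Every EAE array lay above every PBS array, at the rat spots narrowly (-0.300 against -0.309). Each of these 3 differences was smaller than the fall of Actb in the reported fit (1.39). After scaling, the mouse GAPDH 3′ spots differed by 0.24 ± 0.26 (SE) and the 5′ spots by 8.3e-05 ± 0.28. The rat and human spots are named for other species, so their reading of mouse RNA is uncertain. The PGK1 3′ minus 5′ difference was higher by 0.07 at the mouse and 0.57 at the rat spots, with overlap at both. The PGK1 5′ spots had low signal (38.1 to 46.3 for mouse, 39.6 to 47.9 for rat). Where the Actb probe lies in its transcript was not analysed here. A biological difference in the EAE spleens also stays open and was not tested.

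With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3622 called probes, 1 named-gene call and 52 lincRNA calls, where the highest of the other splits gave 0 of each. For the fold of 2 with an unadjusted p under 0.05 it gave 4128 probes, and the highest other split 783. In each of these 4 counts 1 of the 10 splits, the real one, gave as many.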
